A study of Homo sapiens with 8 samples.

How the data were processed

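RNA of MCF-7 cells was measured on 8 Affymetrix arrays, 1 for each of 8 sampled days of estrogen deprivation. Per the labels' protocols, total RNA was amplified and labelled with biotin by a NuGEN FL-Ovation kit. The submitters' processing notes name Partek, without a version or its role. The values deposited by the authors are log2 probe set levels, with a median near 6.04 in each column. Background correction, summarization and normalization between arrays are not given in the sources used here. The 8 columns have near-equal but not identical quantiles. Arrays give no counts, and their number, the background and the choice of probe set limit the precision.

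Probe sets were named with the probe table of the platform and the RefSeq gene table. Of the probe sets, 62 were controls, 41091 had 1 gene symbol, 1801 had several and 11721 had none. For 41037 of the first kind the Entrez ID matched the gene table, and 54 kept the platform's symbol. Each of 19775 genes was represented by its probe set with the highest mean over the 8 arrays, among probe sets of a single symbol. A gene was tested if that mean lay above the median of all probe sets (6.04), which left 12116. Probe sets with several symbols or none were not used for the gene tests. Genes without a probe set of their own, such as AR, STAT1 and PTEN, were not analysed here.

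Samples were grouped by the day in their labels. Time was taken as log2 of the day plus 1, because the days are spread unevenly. The trend was the slope of log2 expression on that scale over 8 arrays in limma 3.58.1 (lmFit and eBayes without variance trend, R 4.3.3), with 6 residual degrees of freedom, and is given as the fitted change from day 0 to day 180. Curved courses were tested with the quadratic term of an orthogonal polynomial (5 residual degrees of freedom), given as the bow in log2 units. The slope over the 7 deprived arrays and a contrast of days 90 to 180 (4 arrays) against days 0 to 30 (4 arrays) were alternatives to the trend. Tests were two-sided, and p values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Every p in the text with a fold or bow is limma's, and every p of a list is from camera in limma. With 1 array per day, p measures the scatter about a smooth course and not between cultures, and serial samples of 1 culture would not be independent. Differences between single arrays are sizes without a p, and a gene was counted at 2-fold or more. The background of an array was taken as its highest value among 24 probe sets for Bacillus genes, which had a median near 3.1 and a highest of 4.89 to 5.19. A fold with an end under it was computed against it and given as at least that size, a choice made after seeing the data.

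There were 21 gene lists, of which 19 had at least 3 tested members. They were estrogen-induced and estrogen-repressed genes, steroid receptors and cofactors, growth factor receptors and AKT signalling, cell cycle and E2F targets, interferon response, luminal epithelial markers, basal and mesenchymal markers, cholesterol synthesis, amino acid and unfolded protein response, BCL2 family and apoptosis, p53 targets, hypoxia and glycolysis, immediate early genes, steroid metabolism, Wnt and Notch targets, the ESR1 neighbourhood, housekeeping genes, and markers of fibroblasts, leukocytes and endothelium. Lists were tested with camera at a preset correlation of 0.01 and again with the correlation estimated from the data, with Benjamini-Hochberg over the 19 lists. At each day the median change of a list was set against 10000 random lists of the same size matched on mean expression in 20 bins. Of the list and day pairs, 66 lay outside the central 95% of the random lists. The percentile describes 2 arrays and is no p.

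Gene order was taken from the RefSeq gene table of GRCh38.p14, and windows of 15 genes were compared with 1000 shuffles of gene order. No positions are printed, since the array table gives no build.

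The named genes follow a rule. They are 27 key genes, the genes past the threshold for the trend (or, where fewer than 3 passed in a direction, the 10 with the largest test statistic), the 6 largest humps and dips, the 10 largest rises and falls at day 3, up to 10 genes sustained in each direction, and up to 4 members of each list with the largest test statistic of the trend. The text names genes from these, and others with a clause that they were chosen after their values were seen. The lists, the tests, this rule and all other settings not named below as added were chosen before the data were examined.

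Alternatives covered the filter (none, or the 75th percentile), quantile normalization, centring of columns, the mean of all probe sets of a gene, days on a linear scale or as ranks, each array left out in turn, other fold thresholds (1.5-fold and 3-fold), other baselines, windows of 10 and 30 genes, and eBayes with a variance trend or robust. Added after seeing the data were the list test of the curvature, estimated correlations for that test and for the deprived slope, the fit without days 3 and 90, windows on the mean of days 120 to 180 minus day 0, values raised to the background, and the estimated correlation in each of the other settings. Against day 0, quantile normalization moved the median change of all genes by at most 0.018 and centring by at most 0.030 log2 units.

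The tests were tried on simulated data with 200 changed genes of 12116. Of changes of 1, 2 and 4 log2 units the trend test recovered 62.7%, 98.5% and 97%, and the curvature test 59.7%, 94% and 93.9%, with 9 and 6 false calls. Without any change both made 0 calls. The simulated scatter was drawn independently for each gene and array, with the size of the scatter about the fitted curve. Real genes move together (estimated correlation 0.92 in the cell cycle list for the trend) and many courses are curved, so these rates need not hold for the real arrays. Of random list and day pairs without a change, again with independent scatter, 6.43% lay outside the central 95%. With shuffled gene order 0 windows lay outside the range, and 18 did after 26 neighbours were raised by 0.7. Of the named genes, 71 had another probe set above the filter, 119 in all, and 4 of these, all of CFLAR, went the opposite way, with a change from day 0 to the mean of days 15 and 30 over 0.3 on both. By that change 8 of the 119, of 6 genes, differed from the probe set used by over 1 log2 unit. Files were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.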

Results

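The series followed MCF-7, an estrogen receptor positive human breast cancer cell line, while it was kept under long-term estrogen deprivation (LTED). Total RNA was measured on 8 Affymetrix arrays, 1 array each for the early days 0, 3, 15 and 30 and the late days 90, 120, 150 and 180, so no time point had a replicate and the number of arrays limits the precision of every value. The series title gives the question as the change of expression during adaptation to estrogen deprivation. The labels give 1 growth protocol, in medium without phenol red and with charcoal-stripped serum, for all 8 arrays, day 0 included, and do not say whether the arrays came from 1 culture. Of 19775 genes named in the deposited table of log2 values, 12116 lay above the level filter and were tested. The medians of the 8 columns lay between 6.01 and 6.07. Across all probe sets, which are not independent replicates, Pearson's r between day 0 and the other arrays was 0.985 for day 3, 0.977 for day 15, 0.974 for day 30, 0.991 for day 90 and 0.988 for day 180. The lowest r between neighbouring arrays was 0.973, between days 30 and 90.

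How far expression had moved from day 0 was asked at each day. At day 3, 422 genes were at least 2-fold higher and 262 at least 2-fold lower than at day 0. The counts were 607 and 587 at day 15, and 765 and 638 at day 30. At day 90 they were 157 and 170, and at day 180 they were 172 and 346. Between days 30 and 90, 1558 genes differed by 2-fold or more, against 64 between days 15 and 30, 63 between days 120 and 150 and 27 between days 150 and 180. Of 255 genes that were at least 2-fold higher on all of days 3 to 30, 156 lay within 2-fold of day 0 on all 4 late days. Of 155 genes that were lower on all of days 3 to 30, 77 lay within 2-fold of day 0 on all 4 late days. These are sizes without a test, and all 7 differences share the day 0 array, so an error in it enters each. The number of genes at 2-fold or more on at least 1 day was 2111 and became 965 with the filter at the 75th percentile of all probe sets. Of the tested genes, 97 read on some day under the background, taken as the highest Bacillus control probe set of that array (4.89 to 5.19). A fold printed below as "at least" was computed against that background, and with all values raised to it the number of genes was 2110.

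**Figure D1:**
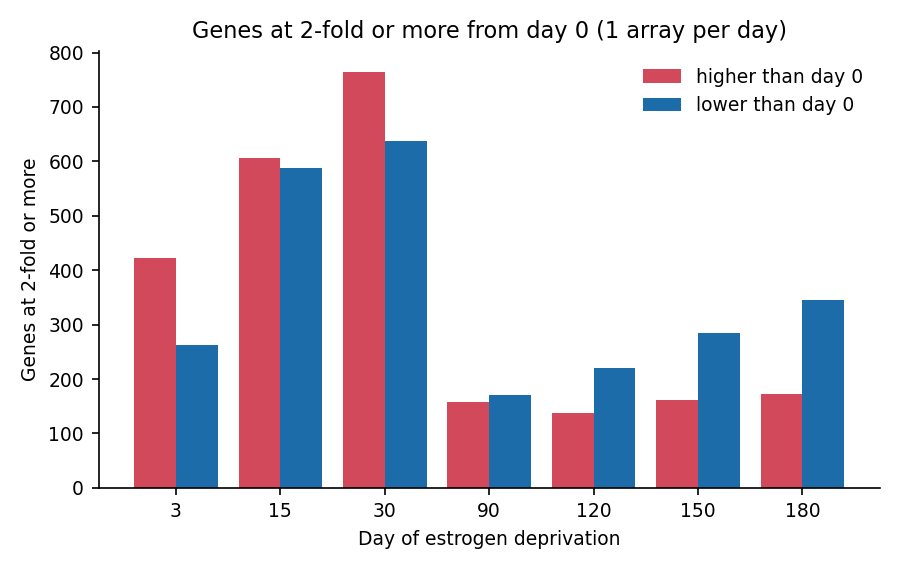
Number of tested genes (of 12116) at least 2-fold higher or lower than day 0 at each sampled day, 1 array per day and day 0 shared by all bars. The counts were highest at day 30 (765 higher, 638 lower) and lower at day 90 (157 and 170).

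The first days of deprivation were read from day 3 against day 0. Estrogen-responsive PGR, the progesterone receptor, was 16.2-fold lower, IGSF1 was at least 34.7-fold lower and ARHGAP36 at least 23.7-fold lower. The secreted proteins MGP, an inhibitor of calcification, and MSMB were 13.1-fold and 12.1-fold lower, HEY2, a transcriptional repressor downstream of Notch, was 12.6-fold lower, and the protease inhibitor SERPINA1 was 11.8-fold lower. The calcium-binding proteins S100A7 and S100A8 were 16.5-fold and 13.8-fold lower, and RGS22 was at least 11.4-fold lower. On the other side, the secreted lectin REG4 was at least 30.1-fold higher, VGLL1, a cofactor of TEAD transcription factors, was 16.8-fold higher, and GABBR2, a subunit of the GABA-B receptor, was 16.3-fold higher. The uroplakins UPK1A and UPK3A, proteins of the bladder surface, were 13.4-fold and 11.9-fold higher. The AP-1 subunit FOSB was 13.9-fold higher, the cytokine TNFSF15 at least 8.04-fold, HOPX 10.6-fold, the keratin KRT4 9.16-fold and the drug efflux pump ABCG2 9.05-fold. By day 180 REG4 was under the background as at day 0, HOPX was 1.06-fold from day 0 and HEY2 1.05-fold. These are differences between single arrays and carry no p.

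A change of at least 2-fold in the same direction on all 7 later arrays was seen for 30 genes, 6 higher and 24 lower. The 6 higher genes were ABCG2, KCTD12, the glutathione peroxidase GPX2, the transcription factor LHX2, the co-repressor TLE4 and RGS16, a regulator of G-protein signalling. At day 180 they stood 2.74-fold, 4.11-fold, 3.70-fold, 2.51-fold, 3.73-fold and 2.04-fold above day 0. Among the lower genes S100A8 was at least 40.1-fold lower at day 180, the stress-induced nuclear protein NUPR1 11.7-fold, the amino acid transporter SLC1A4 8.58-fold and the sarcoglycan SGCE 7.56-fold. CHAC1, which degrades glutathione, was 5.86-fold lower, the transcription factor SOX3 5.20-fold, NBPF4 4.06-fold, the kallikrein KLK11 3.31-fold and ARHGAP36 3.00-fold. PHGDH, the first enzyme of serine synthesis, was 9.96-fold lower at day 30 and 2.70-fold lower at day 180. The day 0 array is shared here too, and the count became 13 with the filter at the 75th percentile.

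Courses that turned were tested with a quadratic term on the log2 scale of days. The bow is the fitted level midway along that scale (day 12.5) minus the mean of the fitted ends, in log2 units ± SE over 8 arrays, so a negative bow is a dip and a positive bow a hump. A number that follows in parentheses is the limma adjusted p. PGR dipped (bow -7.20 ± 0.94, adjusted p = 0.0048), from 11.06 at day 0 to 3.49 at day 30 and back to 10.53 at day 180. The estrogen-regulated genes GREB1 (-4.48 ± 0.58, adjusted p = 0.0048), MYB (-3.95 ± 0.62, 0.0072) and PDZK1 (-3.67 ± 0.38, 0.0032) dipped as well. GREB1 was 34.4-fold below day 0 at day 30 and 2.68-fold below it at day 180, and MYB 16.7-fold and 1.19-fold. The trefoil factor TFF1 dipped by less (-1.52 ± 0.34, 0.018), and so did the estrogen receptor ESR1 (-1.01 ± 0.30, 0.040), which read 12.40 at day 0, 11.51 at day 30 and 12.92 at day 180. The other largest dips were the anterior gradient protein AGR3 (-6.10 ± 0.78, 0.0045), AZGP1 (-5.95 ± 0.66, 0.0035), the RAS-like growth inhibitor RERG (-5.45 ± 0.82, 0.0065), LINC00052 (-5.33 ± 1.22, 0.019) and ARHGAP36 (-5.29 ± 0.34, 0.0017). The largest humps were REG4 (8.08 ± 1.16, 0.0057), HOPX (7.26 ± 1.10, 0.0068), UPK1A (5.95 ± 0.75, 0.0043), the endocytic adaptor DAB2 (5.89 ± 0.66, 0.0035), UPK3A (5.51 ± 0.59, 0.0032) and C2orf72 (5.07 ± 0.64, 0.0043). The sizes and ranks of the bows of PGR, AZGP1, LINC00052, ARHGAP36, REG4 and HOPX rest in part on values under the background.

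**Figure D2:**
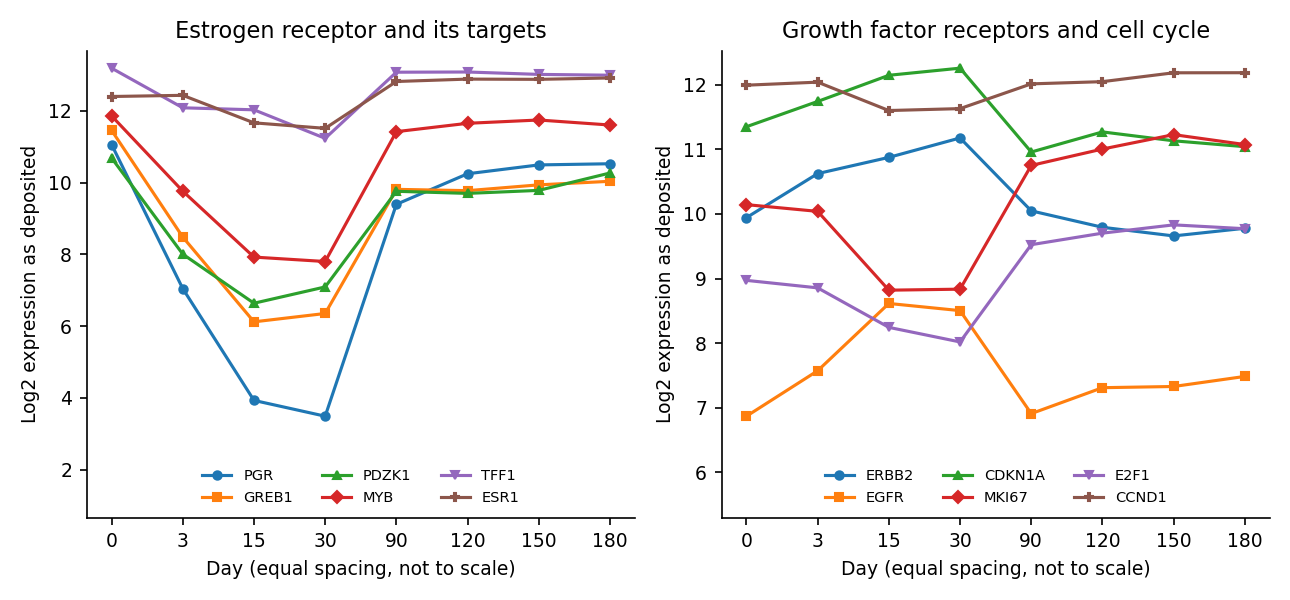
Log2 expression as deposited at each sampled day (days equally spaced, not to scale), 1 array per point. The left panel shows ESR1 and 5 genes regulated by it, with PGR at 3.49 at day 30 and 10.53 at day 180. The right panel shows growth factor receptors and cell cycle genes, with MKI67 at 8.84 at day 30 and 11.07 at day 180.

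Receptors and cell cycle genes fixed beforehand turned in both directions. The receptor tyrosine kinases ERBB2 (bow 1.25 ± 0.20, adjusted p = 0.0075) and EGFR (1.33 ± 0.37, 0.034) humped, ERBB2 reading 9.94 at day 0, 11.18 at day 30 and 9.78 at day 180. The cyclin-dependent kinase inhibitor CDKN1A humped (0.99 ± 0.24, 0.021), while the proliferation marker MKI67 (-1.80 ± 0.42, 0.020), the cell cycle transcription factor E2F1 (-1.27 ± 0.30, 0.021), the kinase AKT1 (-0.37 ± 0.09, 0.026) and the intermediate filament VIM (-1.05 ± 0.30, 0.036) dipped. MKI67 read 10.14 at day 0, 8.84 at day 30 and 11.07 at day 180. The threshold was not passed by CCND1 (-0.44 ± 0.14, 0.056), IRS1 (-0.996 ± 0.32, 0.050), ERBB3 (0.24 ± 0.10, 0.094), FOXA1 (-0.34 ± 0.17, 0.17), IRF1 (0.57 ± 0.38, 0.29), KRT18 (0.12 ± 0.09, 0.33), CXCL12 (-0.97 ± 0.72, 0.34), ERBB4 (-0.59 ± 0.62, 0.50), IGF1R (-0.09 ± 0.11, 0.55), GATA3 (0.07 ± 0.10, 0.64), BCL2 (-0.12 ± 0.18, 0.66) or CDH1 (-0.04 ± 0.09, 0.75). For BCL2 the answer depends on the probe set: the one used changed by 0.01 from day 0 to the mean of days 15 and 30, and its other one above the filter by -2.49. Under some alternatives 3 of these genes did pass as dips: CCND1 with the filter at the 75th percentile (0.042), the mean of all probe sets (0.022) and without day 0 (0.032) or day 3 (0.0076), IRS1 with that filter (0.040), centring (0.047), the mean of probe sets (0.028) and without day 3 (0.013) or day 90 (0.046), and FOXA1 without day 0 (0.048) or day 3 (0.026). In the fit without days 3 and 90, added after seeing the data, all 3 passed, and with values raised to the background IRS1 did (0.0498). The key genes AR and STAT1 had no probe set of a single named gene and were not analysed here. In all, 3546 of 12116 genes passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 1522 as humps and 2024 as dips, and 5236 had an unadjusted p under 0.05. A dip or hump need not end at the day 0 level, as 1525 of the dips lay above it at day 180 and 1072 of the humps below it. Of the dips, 2015 were lowest at day 3, 15 or 30, and 1514 of the humps were highest there. This follows in large part from the test, as these days lie nearest to the middle of the log2 scale. The count depends on the time scale: with days on a linear scale or as ranks limma called 0 genes, with 185 and 761 at an unadjusted p under 0.05, and 2462 and 3541 of the 3546 genes had the same sign as before. Without day 0 the count was 1870, without day 15 1334, without day 30 1508 and without day 150 1998, and the calls of ESR1, EGFR, AKT1 and VIM were each lost in 5 of 8 such fits, those of CDKN1A and LINC00052 in 3, of MKI67 and E2F1 in 2 and of REG4 and TFF1 in 1 (highest adjusted p 0.32, for VIM). Without the level filter ESR1 had an adjusted p of 0.051.

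Gene lists fixed beforehand were followed over the days and tested with camera. The median log2 change of 40 estrogen-induced genes from day 0 was -0.85 at day 3, -1.14 at day 15 and -1.01 at day 30, then -0.14 at day 90 and -0.03 at day 180. At day 30, 37 of the 40 lay below day 0. In the curvature test 29 dipped and 1, the heat shock protein HSPB8, humped (32 and 2 adjusted over the list alone). Besides PGR, GREB1, MYB, PDZK1 and TFF1, the dips held the receptor tyrosine kinase RET (-3.36), the carbonic anhydrase CA12 (-3.54) and the amino acid transporter SLC7A5 (-1.99), chosen after their values were seen. The 14 estrogen-repressed genes went the other way, with a median change of 0.61 at day 3, 1.24 at day 30, 0.05 at day 90 and -0.35 at day 180. Of them 10 humped and 0 dipped (11 and 0 adjusted over the list alone), among them the pro-apoptotic BMF (bow 2.22 ± 0.28, adjusted p = 0.0043), TP53INP1 (0.71 ± 0.14, 0.013) and the cyclin CCNG2 (0.64 ± 0.13, 0.015). The camera adjusted p of the curvature was 5.82e-11 for the induced and 3.50e-07 for the repressed genes, and for both the adjusted p = 0.29 with an estimated correlation. This list test of the curvature was added after seeing the data. RNA quality differed too: the 3' minus 5' difference of ACTB was 1.18 at day 0, 0.81 at day 3, 0.77 at day 15, 1.15 at day 30 and 1.07 to 1.16 on the late days.

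**Figure D3:**
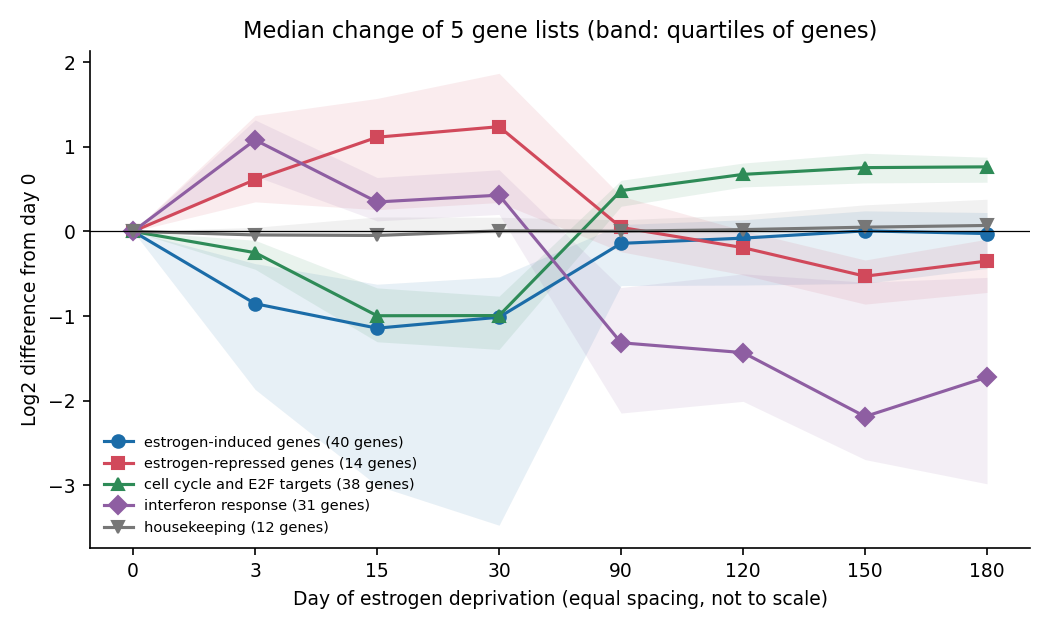
Median log2 difference from day 0 of the tested members of each gene list at each sampled day (days equally spaced, not to scale), 1 array per day and day 0 shared by all points, with bands from the lower to the upper quartile of the genes. The cell cycle list lay at -0.99 at day 30 and 0.76 at day 180, and the interferon list at 1.08 at day 3 and -1.72 at day 180.

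Cell cycle genes were followed next. The median change of the 38 genes from day 0 was -0.25 at day 3, -0.99 at day 30, 0.48 at day 90 and 0.76 at day 180. On the 4 late days 0 of the 38 lay below day 0. In the curvature test 34 dipped (36 adjusted over the list alone), among them the replication helicase subunit MCM6 (-1.01 ± 0.23, adjusted p = 0.019), the ribonucleotide reductase RRM1 (-0.88 ± 0.17, 0.011) and the origin licensing factor CDC6 (-1.23 ± 0.36, 0.040). The mitotic kinases AURKB (-2.43) and PLK1 (-1.92), chosen after their values were seen, also dipped. CCNE1 did not pass (0.01 ± 0.10, 0.94). With camera the adjusted p was 7.25e-12 for the curvature and 6.12e-08 for the upward trend, against an adjusted p = 0.61 and adjusted p = 0.56 with an estimated correlation. For the trend itself 0 members passed, over all genes or adjusted over the list alone.

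Interferon response genes lay above day 0 early and below it late. The median change of 31 genes was 1.08 at day 3, 0.35 at day 15, 0.43 at day 30, -1.32 at day 90, -2.19 at day 150 and -1.72 at day 180, when 30 of the 31 lay below day 0. Over the 7 deprived arrays 25 of the 31 fell (29 adjusted over the list alone), the list's camera adjusted p being 1e-22, and adjusted p = 0.29 with an estimated correlation. BST2, a membrane protein that tethers virus particles, fell by 4.86 ± 0.26 log2 units from day 3 to day 180 (adjusted p = 0.0037). The RNA-activated synthetase OAS2 fell as well (0.011), to under the background at day 180, at least 7.72-fold below day 0. IFI27 fell by 5.27 ± 0.73 (0.023) and the RNA sensor RIGI fell by 3.93 ± 0.61 (0.030). IFIT1, chosen after its values were seen, read 9.75 at day 0, 11.07 at day 3 and 3.96 at day 180, then at least 27.0-fold below day 0. In the curvature test 24 of the 31 humped (25 adjusted over the list alone; camera adjusted p 9.68e-13, adjusted p = 0.29 with an estimated correlation). In the trend over all 8 arrays 0 passed over all genes and 23 fell adjusted over the list alone, with a camera adjusted p of 2.49e-20 and an adjusted p = 0.56 with an estimated correlation.

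Cholesterol synthesis genes trended up (camera adjusted p 0.0025, 5 of 19 genes up adjusted over the list alone and 0 over all genes, adjusted p = 0.56 with an estimated correlation), and the transferase ACAT2 rose by 1.56 ± 0.19 from day 3 to day 180 (adjusted p = 0.016) and DHCR7, the last enzyme of the pathway, rose too (0.017). Over the deprived arrays 3 genes of this list rose and 1, SC5D, fell (-0.93 ± 0.19, 0.046; 6 and 1 adjusted over the list alone). The 20 genes of the amino acid and unfolded protein response trended down (0.044, adjusted p = 0.58 with an estimated correlation), and 5 dipped (5 adjusted over the list alone): PHGDH (-2.40 ± 0.22, 0.0022), CHAC1 (-1.15 ± 0.25, 0.016), ASNS, TRIB3 and SHMT2. As lists, neither this one (0.23) nor cholesterol synthesis (0.67) passed for the curvature. Immediate early genes had a median change of 0.82 at day 3, 0.44 at day 30 and -0.31 at day 180 and trended down (0.0035, adjusted p = 0.56 with an estimated correlation), FOS falling by 1.63 ± 0.23 over the deprived arrays (0.025), and 5 of 13 humped (5 adjusted over the list alone; list adjusted p 1.97e-04, adjusted p = 0.29 with an estimated correlation). The trend of cholesterol synthesis had an adjusted p of 0.067 without day 0, 0.19 with days on a linear scale and 0.28 in the 2 windows of early and late days. That of the amino acid list was 0.90 without day 0, where the test pointed up instead of down, 0.074 without day 90, 0.10 without day 180, 0.19 with the filter at the 75th percentile, 0.38 with linear days, 0.13 with ranks and 0.50 in the 2 windows. Without day 3 that of the immediate early genes was 0.15. The estrogen-repressed list also trended down (0.0030, adjusted p = 0.56 with an estimated correlation), so 7 of 19 lists passed for the trend (limma, Benjamini-Hochberg) and 0 with an estimated correlation. In the trend test 0 members of these 4 lists passed over all genes, and adjusted over the list alone 0 passed apart from the 5 of cholesterol synthesis.

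Lists that did not pass for the trend were the estrogen-induced genes (adjusted p = 0.17), steroid metabolism and p53 targets (both 0.077), BCL2 family and apoptosis (0.20), growth factor receptors and AKT signalling (0.29), basal and mesenchymal markers (0.29), luminal epithelial markers (0.56), housekeeping genes (0.56), steroid receptors and cofactors (0.62), Wnt and Notch targets (0.62), fibroblast markers (0.79) and hypoxia and glycolysis (0.99). The estrogen-induced list passed upward with days on a linear scale (5.33e-04) or as ranks (0.013), without day 0 (2.71e-06) and in the 2 windows (1.27e-04), and with an estimated correlation it passed in none of these (adjusted p = 0.71, 0.69, 0.62 and 0.57). The p53 list passed downward without a filter (0.035) and without day 120 (0.032), and steroid metabolism upward without day 180 (0.010), against 0.63, 0.55 and 0.48 with an estimated correlation. None of these 12 passed for the curvature with the exception of the estrogen-induced genes. Median and mean trend differed in sign for the growth factor list (-0.05 and 0.02, test down), the luminal list (0.01 and -0.02, test down) and the hypoxia list (-0.0042 and 0.0023, test down). Inside the growth factor list 4 of 26 humped and 4 dipped (6 and 5 adjusted over the list alone), the dips including the fibroblast growth factor receptors FGFR4 (-1.61 ± 0.17, 0.0033) and FGFR1 (-1.12 ± 0.17, 0.0070). The p53 list had 6 humps and 3 dips of 17 (7 and 4 adjusted over the list alone), the BCL2 family list 6 and 2 of 17 (7 and 2), the hypoxia list 3 and 3 of 19 (4 and 3), the Wnt and Notch list 5 and 3 of 17 (5 and 3), the luminal list 2 and 2 of 22 (2 and 1) and the steroid receptor list 2 and 4 of 13 (2 and 5). The basal and mesenchymal list had 4 and 2 of 12 (4 and 2), cholesterol synthesis 1 and 3 of 19 (1 and 3), steroid metabolism 1 and 1 of 11 (1 and 0), housekeeping genes 1 and 1 of 12 (0 and 1) and fibroblast markers 0 and 0 of 3 (0 and 0). Among the curvatures, median and mean differed in sign for the luminal (0.07 and -0.13), hypoxia (-0.04 and 0.21), steroid metabolism (-0.12 and 0.09), Wnt and Notch (0.13 and -0.16) and housekeeping lists (-0.02 and 0.01), the test pointing up for all 5. Among markers of other cell types, the fibroblast list had 3 tested members with a median change of 1.10 at day 15 (percentile 98.6 of random lists), 1.18 at day 30 (97.95) and 0.27 at day 180, the endothelial list 2 (PECAM1, 8.61 at day 0 and 6.60 at day 180, and ENG, 6.49 and 6.57) and the leukocyte list 1 (LCP1, 8.43 and 8.01), the last pair being too few for a test.

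A steady trend over all 8 arrays was asked next, as the fitted change from day 0 to day 180 on the log2 scale of days. The palmitoyltransferase ZDHHC2 rose by 1.37 ± 0.13 log2 units, from 7.73 to 9.08. The sarcoglycan SGCE fell by 2.47 ± 0.24, from 10.56 to 7.64, and the non-coding RNA LINC01503 fell by 1.23 ± 0.12, from 9.76 to 8.48. All 3 had an adjusted p of 0.037, and no other gene passed (limma, Benjamini-Hochberg; 1417 at an unadjusted p under 0.05). Genes with the next largest test statistics did not pass: CORO1A, an actin-binding protein (1.12 ± 0.14), ZNF527 (1.33 ± 0.17) and DHRS13 (0.97 ± 0.12) with an adjusted p of 0.10, the CTP synthase CTPS2 (-0.86 ± 0.12) with 0.15 and the transcription factor NFIA (-3.66 ± 0.52, 10.19 at day 0 and 5.99 at day 180) with 0.17. Positive changes without a call were also seen for PLXDC2 (2.39), the tubulin TUBB4B (0.67), the enolase ENO2 (0.74), the galactokinase GALK1 (0.79), SPIDR (0.76) and XYLB (0.78), and negative ones for ZNF33B (-0.79), SYF2 (-0.78), PPM1K (-1.45), RIPOR3 (-1.39), FCGR2A (-0.99) and LOC100996740 (-1.49). The count depends on the fit: 1458 genes passed with days on a linear scale, 6 with ranks, none of them these 3 (each with an adjusted p of 0.079), and 0 with a variance trend in eBayes, with 1426 at an unadjusted p under 0.05. With the mean of all probe sets of a gene ZDHHC2 had an adjusted p of 0.32. Leaving out day 0 gave 564 genes, leaving out day 3 or day 120 gave 1, and leaving out day 15, 30, 90, 150 or 180 gave 0 (1321, 1790, 1369, 751 and 761 at an unadjusted p under 0.05). In these 8 fits the calls of ZDHHC2 and LINC01503 were each lost in 7 and that of SGCE in 6, and without day 3 none of the 3 passed (0.055, 0.18 and 0.13).

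Changes within deprivation were asked by leaving out day 0 and by setting the late arrays against the early ones. Over the 7 deprived arrays 564 genes passed (limma, Benjamini-Hochberg), 266 rising and 298 falling from day 3 to day 180. PLXDC2 rose by 2.39 ± 0.24 (adjusted p = 0.014), CORO1A by 1.03 ± 0.11 (0.016) and FGFR4 by 2.14 ± 0.41 (0.041), while GABBR2 fell by 3.64 ± 0.58 (0.030), NFIA fell by 2.98 ± 0.56 (0.041), SNAI2, a mesenchymal transcription factor, fell by 3.12 ± 0.57 (0.039) and the LIM protein FHL2 fell by 1.39 ± 0.14 (0.014). Among the estrogen-repressed genes 5 fell (10 adjusted over the list alone), among them BMF (-2.80 ± 0.58, 0.047), TP53INP1 (-1.15 ± 0.20, 0.036) and CCNG2 (-1.01 ± 0.22, 0.0498). Of the estrogen-induced genes 2 rose and 1 fell (14 and 1 adjusted over the list alone), and of the cell cycle genes 0 passed either way. With camera 6 of 19 lists passed for this slope and 0 with an estimated correlation, the lowest being adjusted p = 0.13 with an estimated correlation, for the immediate early genes. Between the 4 arrays of days 90 to 180 and the 4 of days 0 to 30, 2511 genes differed, 1477 higher and 1034 lower in the late arrays. SGCE did not pass there, with an adjusted p of 0.056.

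Whether neighbouring genes moved together was asked in windows of 15 consecutive tested genes, placed by gene order on the assembly GRCh38.p14, since the array table gives no genome build. Of 11771 windows over 12093 placed genes, 27 had a median trend above and 23 below the shuffled range (-0.63 to 0.64). A small share of the 1000 shuffles of gene order went beyond that range too. The highest medians lay on chromosome 8, in runs from LZTS1 to DPYSL2 (35 genes, median change 0.64) and from RBPMS-AS1 to RAB11FIP1 (17 genes, 0.71), and on chromosome 6 from KATNA1 to ARID1B (21 genes, 0.47), a run that holds ESR1. Low runs lay on chromosome 10 from AGAP11 to MARCHF5 (29 genes, -0.64), on chromosome 4 from BOD1L1 to SEPSECS (20 genes, -0.66) and on chromosome 3 from DUBR to CFAP44 (16 genes, -0.68). The fixed list of genes around ESR1 had a median change of -0.05 at day 30 and 0.39 at day 180, 9 of 23 dipped and 1 humped (9 and 1 adjusted over the list alone), and it trended up (camera adjusted p 0.0040, adjusted p = 0.56 with an estimated correlation; curvature 0.033, adjusted p = 0.61 with an estimated correlation). For the trend 0 of its members passed, over all genes or adjusted over the list alone. The 15 tested genes on each side of ESR1 had a median trend of 0.35. With the mean of days 120 to 180 minus day 0, a measure chosen after seeing the data, 46 of 52 genes from INTS10 to HMBOX1 on chromosome 8 lay above day 0 (median 0.52), 29 of 32 from HS3ST1 to PGCKA1 on chromosome 4 lay below (-0.52) and 24 of 28 from GLUD1 to MARCHF5 on chromosome 10 lay below (-0.48), a run that holds 4 IFIT genes. On this measure no window on chromosome 6 lay beyond the shuffles, so the run around ESR1 was seen only as a trend, and so were those from DUBR to CFAP44 and from RBPMS-AS1 to RAB11FIP1. The median of the chromosome 8 genes was -0.01 at day 3, -0.06 at day 30, 0.11 at day 90, 0.50 at day 120 and 0.51 at day 180. The number of windows outside the range was 26 without day 180 or with windows of 10 genes and 236 with windows of 30 genes.

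**Figure D4:**
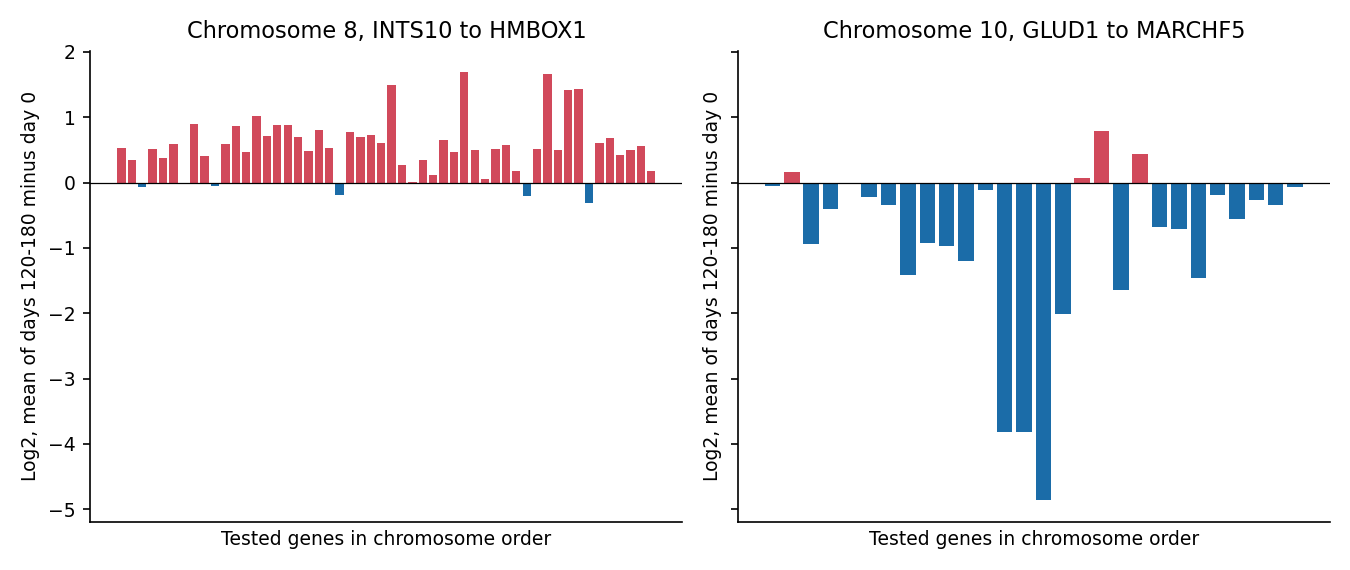
Mean of days 120 to 180 minus day 0 (log2) for consecutive tested genes in runs of neighbouring genes, 1 bar per gene in chromosome order, red above and blue below day 0, the late mean over 3 arrays and day 0 from 1. On chromosome 8, 46 of 52 genes lay above day 0, and on chromosome 10, 24 of 28 lay below.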

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

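Of the tests below, the counts over other orders and splits of the arrays, except those for lists with a curvature, and the test of interferon genes inside the chromosome 10 region were chosen beforehand, and the others only after the result was seen.

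Estrogen-induced and cell cycle genes lay low from day 3 to day 30 and near or above day 0 from day 90. A difference in RNA quality or amplification between arrays is left open. The 3' minus 5' difference of ACTB was 1.07 to 1.18 at day 0 and on the late days. It lay outside that range at day 3 (0.81) and day 15 (0.77) and inside it at day 30 (1.15). That of GAPDH lay outside its range (0.051 to 0.075) at each of these days (0.033, 0.024 and 0.093). The 28S control lay inside its range (6.93 to 8.62) at each (7.61, 8.36 and 7.73). With fewer dividing cells as the whole cause, the cell cycle list was taken to fall at least as far at day 3. The induced list lay lower than it by a difference of medians of -0.60 (95% bootstrap interval over genes -1.19 to -0.28). This argues against that cause for days 0 and 3 only, with 1 array each. The interval takes genes that move together as independent and does not cover arrays or cultures. RNA quality differed at day 3 as well. That the late arrays came from cells that had estrogen again, or from another MCF-7 stock, cannot be told apart from adaptation, since an induced list median of -0.025 at day 180 follows from each and the labels give 1 growth protocol for every array.

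Interferon response genes lay below day 0 on all 4 late days. The smallest gap between day 0 and a late array was -1.32, larger than the range of 0.87 among the late arrays. This restates the pattern and cannot tell whether the day 0 array was swapped with a late one. Such a swap and a single wrong label both stay open. Loss of the chromosome 10 region with the IFIT genes is not the whole cause, as the 27 members on other chromosomes had a median change of -1.41 at days 120 to 180. No biological explanation of it was tested.

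Neighbouring genes moved together between day 0 and the late arrays. Around ESR1 no window lay beyond the shuffles in the mean of days 120 to 180 minus day 0, but only in the trend. Over the tested neighbours as a set, the higher level at days 120 to 180 does not rest on CCDC170, DCPH1, RMND1 and FBXO5. Without them the median change was 0.24, at the 99.95th percentile of random gene sets. The windows of the trend were not run again without these genes, so whether that run rests on them is left open. On chromosome 10 the low run in the trend over all arrays does not rest on IFIT1, IFIT2, IFIT3 and IFIT5. Without these the lowest window median of the trend was -0.97, below the shuffled limit of -0.62. No other genes of the run were taken out, and the windows on the late means were not run again. A change in DNA copy number may account for these runs, such as the median change of 0.52 from INTS10 to HMBOX1, but it cannot be told apart from regional control of expression without a measurement of DNA.

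Whether the order of the days could give such counts by chance was asked by giving the days to the arrays in 100 orders, the real one included. For the curved courses (3546 genes) 2 orders, the real one included, were as high or higher. The highest other gave 3841, in an order that also keeps days 3, 15 and 30 next to each other. For the slope over the 7 deprived arrays (564 genes) 1 order, the real one, reached the count, the highest other being 497. For the 2 windows (2511 genes) 1 of 35 splits, the real one, reached the count and the highest other was 48. Such counts were rare when the days were given to the arrays at random. The orders treat the arrays as exchangeable, so they cannot tell a course over time from a culture or batch shared by neighbouring days. They were tried on the log2 scale of days only, and with linear days or ranks the real order gave 0 curved genes. For the trend (3 genes) chance cannot be excluded, with 6 orders, the real one included, as high or higher. The highest other gave 4503 genes, which points to a structure of the samples. Nor can chance be excluded for the lists with a trend (7 lists, 13 orders, highest other 9) or with a curvature (6 lists, 41 orders, highest other 9). Both of these counts of orders hold the real one too.

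The following stand out because the early arrays (days 3 to 30) and the late arrays (days 90 to 180) lay on opposite sides of day 0. This rule is no test in itself. The tests that bear on it are the slope over the deprived arrays and the contrast of late and early windows, described above. The late mean minus the early mean was 1.42 for the cell cycle list, -2.28 for the interferon list and 0.42 for the ESR1 neighbourhood list. Among key genes it was 1.78 for MKI67, 1.33 for E2F1, 0.35 for AKT1, -0.26 for ERBB3 and -0.95 for CDKN1A. Outside the gene tests, among 4593 probe sets without a single named gene that lay above the filter, 907 (19.7%) had a curved course with limma, 519 as humps and 388 as dips.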

How the results depend on the processing

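The list tests of the curvature, both estimated correlations beside it, the fit without days 3 and 90, the windows on late means, the values raised to the background and the estimated correlation within each other setting were chosen after seeing the data. No paired analysis was possible because each day had 1 array and no replicate numbers link samples. Of the values for named genes under alternatives, 518 kept direction and side of the threshold, 106 lost and 15 gained a call and 14 reversed. For single lists, by the sign of the mean trend, the numbers were 288, 20, 8 and 24. Summary counts stayed within 1.5 times in 74 cases and moved beyond it in 33, and the counts of single days at 2-fold in 24 and 11, 7 of these with the stricter filter and 4 with the mean of all probe sets. The filter acts on the mean level, so genes dim on single days remained, with sizes that are uncertain. The cause of the changes below was not tested, except where fewer genes or arrays, another fold threshold or a new window size made the count.

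With days on a linear scale the trend gave 1458 genes and the curvature 0, and the bow reversed for REG4 (-0.18), GATA3 (-0.0050), EGFR (-0.048), ERBB3 (-0.038), ERBB4 (0.16), E2F1 (0.0024), IRF1 (-0.31) and CDKN1A (-0.0095) and the mean trend of the luminal (0.032), hypoxia (-0.084) and fibroblast lists (-0.58). With ranks the trend gave 6 genes and the curvature 0, and the luminal (0.0077), hypoxia (-0.028) and fibroblast lists (-0.35) reversed. With each array left out in turn the trend gave 0 to 564 genes, the curvature 1334 to 4583 and the windows 26 to 61 beyond the shuffles. Over these fits the bow reversed without day 0 for CXCL12 (-1.60 to 0.92), BCL2 (-0.39 to 0.14), GATA3 (lowest -0.046), IGF1R (-0.17 to 0.032) and IRF1 (-0.36 to 0.83), and without day 30 for ERBB4 (-1.13 to 0.067). The luminal list reversed without day 0 (-0.074 to 0.12), the hypoxia list without day 0 or day 30 (-0.13 to 0.047; -2.2e-04 without day 30) and the fibroblast list without day 0, day 3 (-0.30) or day 150 (-0.0094; range -0.37 to 0.37). Over the 7 deprived arrays, which is the fit without day 0, 564 genes had a slope, and the luminal (0.12), hypoxia (-0.13) and fibroblast lists (-0.37) reversed. The stricter filter reversed the growth factor (-0.029) and hypoxia lists (-0.025), the mean of all probe sets the growth factor (-0.028) and luminal lists (0.026), quantile normalization the hypoxia list (-0.0067) and centring the luminal list (0.0085). None of the reversed values passed the threshold. The direction of the camera test, which need not be the sign of the mean, turned for 15 list values, 0 of them past the threshold, among them the amino acid list without day 0. The 2 windows gave 2511 genes (luminal list 0.032, hypoxia list -0.11, fibroblast list -0.47), a variance trend in eBayes 0, and the fit without days 3 and 90 gave 5436 curved genes. With an estimated correlation 0 lists passed for the trend, 0 in each of the other settings, 0 for the curvature and 0 for the deprived slope. Windows of 10 genes gave 26 and of 30 genes 236 beyond the shuffles. Genes at 2-fold on at least 1 day numbered 965 with the filter at the 75th percentile, 5032 at 1.5-fold and 850 at 3-fold, and sustained genes 13, 105 and 5.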

Other observations

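The genes below were chosen after their values were seen, and no test beyond those already described was run on them. Several mesenchymal and basal genes humped while others dipped. The transcription factor SNAI2 (bow 2.40 ± 0.48, adjusted p = 0.013), the caveolae proteins CAV1 (2.68 ± 0.75, 0.035) and CAV2 (1.58 ± 0.34, 0.016) and the matrix protein fibronectin FN1 (2.33, 0.013) humped, while VIM and the integrin ITGA6 (-1.16, 0.011) dipped. CAV1 read 10.07 at day 0, 11.73 at day 30 and 8.21 at day 180. The glucocorticoid receptor NR3C1 humped by 2.54 (8.23e-04), 4.85-fold above day 0 at day 30 and 1.17-fold from it at day 180, and the phosphatase DUSP1, an immediate early gene, by 2.77 (0.0028). The chaperone HSPB8 of the estrogen-induced list humped by 3.82 (0.0021).

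A small set of genes stayed within 2-fold of day 0 on days 3 to 30 and lay at least 2-fold away on all 4 late days, 11 higher and 22 lower. The higher ones held the cyclin CCNA1 (8.04 at day 180 and 5.35 at day 0) and, with their median late changes, the centromere protein CENPI (1.702), GINS4 of the replicative helicase (1.68), CDC6 (1.63) and CLSPN, an S-phase checkpoint protein (1.39). They also held PLXDC2 (1.77), SYNPO2 (1.76), TNFRSF19 (1.45), ZDHHC2 (1.39) and FAM111B (1.32). The lower ones held the interferon genes IFIT2 (-3.89), IRF9 (-2.37), RIGI (-2.30) and OASL (-2.18), and FILIP1L (-3.21) and S100A2 (-2.39). On chromosome 1, 17 of 18 genes from S100A11 to CHTOP, which hold S100 and small proline-rich genes of keratinized epithelium, lay below day 0 in the mean of days 120 to 180 (median -0.31), several of them by about 0.1 and others by far more, with S100A8 at -5.51 and SPRR1B at -4.23. These are sizes without a test and share the day 0 array. IFIT2, S100A8 and SPRR1B read under the background on some late days, and with values raised to it IFIT2 stood at -3.56, S100A8 at -5.25 and SPRR1B at -3.81.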
